A study of Bos taurus with 24 samples.

How the data were processed

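Small RNA was sequenced from the fetal and the maternal part of the placenta of Finnish Ayrshire cattle (Bos taurus), from pregnancies ended on day 94 ± 12 of gestation. The fetuses were either wild type or carried a deletion of MIMT1, a long non-coding RNA gene of the imprinted PEG3 domain, on 1 of the parental chromosomes. Each of the 12 pregnancies, 7 with a wild-type and 5 with a deletion fetus, gave 1 library of each tissue, which made 24 libraries. The genotype is that of the fetus, so a maternal library is grouped by the fetus the cow carried. Total RNA was extracted with a column kit and libraries were made with the TruSeq small RNA kit, per the labels' protocols. The submitters' processing notes name FastQC without a version. Adapter trimming, the aligner, the counting rule, the genome build and the miRNA annotation release are not given in the sources used here.

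The authors deposited 2 tables, 1 per tissue, with a whole-number count for each unique sequence in each library, per the file headers. Each sequence carries the symbol of 1 miRNA gene. The fetal table lists 1070 sequences of 290 mature miRNAs, the maternal one 1024 sequences of 265, and 871 sequences stand in both. Sequences are 17 to 34 nt long. The lowest total count of a listed sequence was 208 in the fetal and 187 in the maternal table, so low sequences had been removed before deposit and no statement is made on miRNAs that are not listed. The authors also deposited log2 fold changes and log2 mean CPM per sequence, which per the file headers come from a likelihood ratio test in the layout of edgeR. Their p-value and FDR columns were deposited beside these, and the FDR equalled a Benjamini-Hochberg adjustment over all sequences of the table. The deposited normalised columns were not used. Every per-sample count column was matched to a library by the group and number in its name, and 0 columns were left without a sample.

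Counts of a library were summed per mature miRNA. Arms are named by the files where the symbol gives them. Where a gene showed sequences of both arms, sequences were assigned to an arm by a shared word of 9 nt, and the less abundant arm is named here with the ending minor. Of 1223 sequences in either table, 133 were marked canonical. The one with the most counts per miRNA served as its reference and makes up the canonical class, of 121 sequences. The remaining sequences of these miRNAs were classed by their ends relative to it, among them 12 that were marked canonical, 10 shorter and 2 longer at the 3' end, and 493 sequences belonged to miRNAs without one and form a class of their own. miRNAs with near-identical copies, such as the let-7 and miR-30 families, can share reads, and how the authors divided these is not given in the sources used here. The table of bovine genes at hand holds no entry for the unnamed genes ENSBTAG00000047329 and ENSBTAG00000047154, so no genome position is printed.

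The main test was the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, in R 4.3.3) with TMM factors and filterByExpr, and Benjamini-Hochberg adjustment over all miRNAs or sequences tested, with a threshold of 0.05. Deletion was compared with control within each tissue, per miRNA and per sequence. The difference of the deletion effect between tissues, and fetal against maternal placenta, were fitted over all 4 groups on the 245 miRNAs of the sequences present in both tables. Levels are counts scaled to TMM-adjusted library totals (CPM), given as mean ± SD. Errors of log2 fold changes are standard errors. Shares of each library's counts by sequence class were compared with a two-sided exact permutation test over all 792 arrangements of 7 and 5 libraries. All 21 lists of miRNAs, of which 9 mark cell types, were written before the data were examined, as were the tests, the main designs, most of the alternative settings and the rule for naming miRNAs. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a tissue. The same tests of the lists between tissues were added after the data were examined.

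The naming rule took, for each deletion comparison, up to 12 miRNAs per direction past the threshold, and where fewer than 10 passed, the 10 of smallest p. It also took the 10 most abundant miRNAs of each tissue, the 2 to 4 most abundant members of each list, and miR-210, miR-675, miR-483, miR-335 and miR-122 where detected. For the tissue comparison it took the 12 of largest fold per direction among those past the threshold with at least 100 CPM in the higher tissue. For single sequences it took up to 5 per direction past the threshold, and for the difference between tissues up to 10. Other names were chosen after their values were seen and are said to be so.

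Library totals ran from 293969 to 1785650 counts. Reads without molecular identifiers are not independent molecules, and the tests rest on the spread between pregnancies as well as on counting error. No 2 libraries of a tissue were alike enough to be the same library, the highest correlation of log2(count + 1) being 0.984. In data simulated from the real means and library sizes, with 200 changed features of log2 fold 1 or 2, the fetal miRNA test recovered 68% and 97%, the maternal miRNA test 61% and 97%, and the fetal and maternal sequence tests 56% and 95%, and 32% and 94%. The simulated difference between tissues was recovered for 53% and 96% of changed miRNAs and the simulated tissue comparison for 94% and 100%. The 200 changed features were most of the 290 fetal, 265 maternal or 245 shared miRNAs, and adjustment is more lenient when most features change. Counts were drawn independently for each feature, without any division of the pregnancies. Recovery with few changed miRNAs was not measured and can be lower.

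The title of each library carries a number, and the same 12 numbers stand in both tissues with the same genotype, so libraries of equal number were taken as 1 pregnancy and as paired. Their deviations from the group means correlated with r from 0.269 to 0.708 in 11 of 11 pairs without pregnancy 13. With pregnancy 13 included, r ran from -0.814 to 0.708, and 10 of 12 pairs lay above 0.1. The replicate block was an alternative to the main fit. Other alternative settings fixed in advance were size factors by median ratio, library totals alone, DESeq2 1.42.0, limma-voom with quality weights, other filters on low counts, canonical sequences alone, an estimated inter-gene correlation, fry, and leaving out each replicate. Files held counts, so no pseudocount alternative applied, and each sequence carries 1 symbol, so leaving out sequences of several miRNAs could not be run.

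Principal components were computed on log2 CPM of the 245 shared miRNAs, and 2 sets of pregnancies were read from the sign of the second component. They were read again from the first component of each tissue alone, after the data were examined. Fits with a term for the set, within each set, without pregnancy 13 together with these or with the replicate block, and by the likelihood ratio test with and without outlier-robust dispersions were added after the data were examined, as were list tests that combined an estimated correlation with the set term or with leaving out a replicate. The check for a library that stands apart used Dixon's ratio within each group of 5 or 7 libraries, 224 groups in all. It covered the levels of miRNAs named otherwise than through a list, with those of the tissue comparison scaled over both tissues. Library totals, the share of sequences that resemble ribosomal RNA and the class shares were covered as well. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.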

Results

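miRNAs of both sides of the bovine placenta were profiled by small RNA sequencing in pregnancies with a wild-type fetus (control) and pregnancies with a MIMT1Del/WT fetus (deletion). The series addressed the placenta of growth-restricted fetuses. Counts per library averaged 793335 ± 295773 (SD, n = 7, from 420033 to 1306307) in control fetal placenta and 626487 ± 234977 (n = 5, from 359182 to 948580) in deletion fetal placenta. In maternal placenta they averaged 886399 ± 349592 (n = 7, from 293969 to 1373150) in controls and 1085220 ± 509462 (n = 5, from 382206 to 1785650) with a deletion fetus. MIMT1 itself is not measured in miRNA tables, so the genotype labels could not be checked against the deleted gene. The most abundant miRNAs were miR-27b and miR-10b in fetal placenta and miR-10b and miR-143 in maternal placenta. The main sequence of miR-10b, TACCCTGTAGAACCGAATTTGT, made up 69.1% of its fetal counts, and that of miR-27b, TTCACAGTGGCTAAGTTCTG, 46.2%.

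Tissue was the first difference between libraries and a division of the pregnancies the next. The first principal component held 63.2% of the variance of the 245 miRNAs measured in both tissues and separated fetal from maternal libraries except those of control pregnancy 13. On an axis from the mean of the other fetal libraries (0) to the mean of the other maternal libraries (1), the library labelled fetal 13 lay at 0.980 and the library labelled maternal 13 at 0.0554. The 11 other fetal libraries lay between -0.0588 and 0.0450 and the 11 other maternal libraries between 0.786 and 1.27. The second component (17.5%) parted the pregnancies into a set of 6 (13, 14, 15, 19, 20 and 22) and another 6 (17, 18, 23, 24, 25 and 26), called set 1 and set 2. Both libraries of a pregnancy lay on the same side in 12 of 12 pregnancies (exact permutation p = 0.00108 over 924 arrangements). Read from the first component of fetal or of maternal libraries alone, without pregnancy 13, the sets were the same for 11 of 11 pregnancies (exact permutation p = 0.00216 over 462 arrangements). Set 2 held 4 of the 5 deletion and 2 of the 7 control pregnancies (Fisher's exact p = 0.242). The sets are sets of samples defined from these values and not groups of the study.

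**Figure D1:**
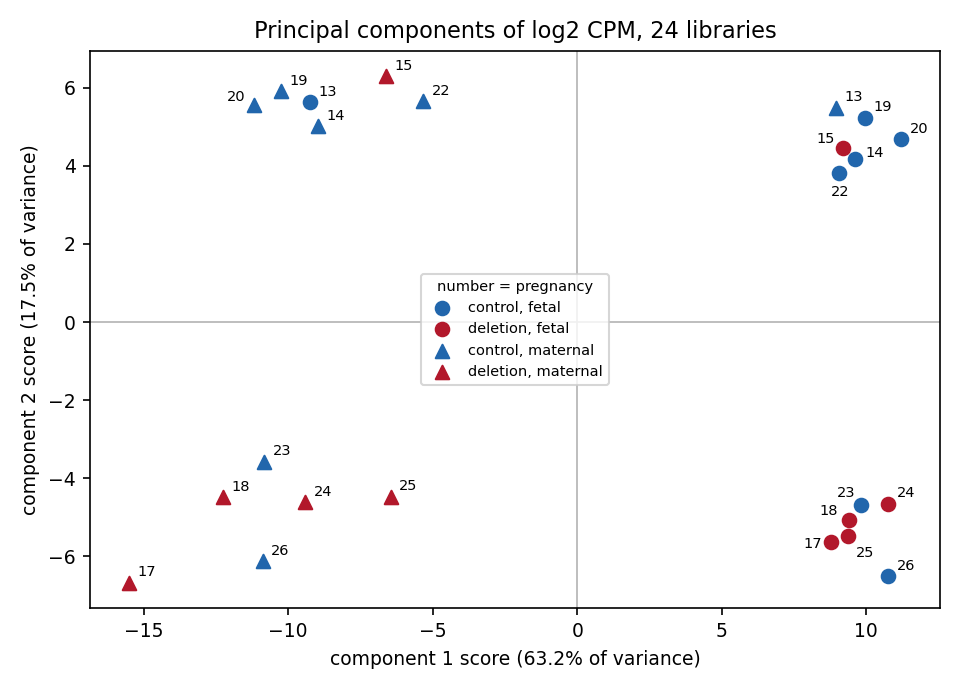
Position of each of the 24 libraries on the first and second principal component (unitless scores, with the percent of variance on each axis) of log2 CPM of 245 miRNAs, by genotype and tissue. The library labelled fetal 13 sits among the maternal libraries and the library labelled maternal 13 among the fetal ones, and the second component parts 6 pregnancies from the other 6 in both tissues.

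Fetal and maternal placenta were compared over all 12 pregnancies. miRNAs of the DLK1-DIO3 cluster, an imprinted domain that expresses its miRNAs from the maternal chromosome, were higher in fetal placenta, whereas miRNAs of smooth muscle and stroma, of the HOX clusters and of the let-7 family were higher in maternal placenta. These group shifts passed a list test with a preset correlation and none passed with an estimated one, where the adjusted p ran from 0.129 to 0.210 without pregnancy 13. miR-410 of the DLK1-DIO3 cluster stood at 6283 ± 2186 CPM in fetal against 1490 ± 836 CPM in maternal placenta (SD, n = 12 each; log2 fold change 2.11 ± 0.28 SE). miR-10a and miR-10b, which lie within HOX gene clusters and follow position along the body axis, were lower in fetal placenta, miR-10a at 1745 ± 3023 against 14058 ± 7214 CPM (-3.22 ± 0.60) and miR-10b at 65735 ± 46396 against 248204 ± 115004 CPM (-1.97 ± 0.29). edgeR's quasi-likelihood test placed 163 of 245 miRNAs past the threshold, 83 higher and 80 lower in fetal placenta, with a smallest adjusted p of 8.26e-06.

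In the DLK1-DIO3 list 29 of 33 measured members were higher in fetal placenta and 0 lower, with a median log2 fold change of 0.98 (camera adjusted p = 7.85e-10; adjusted p = 0.129 with an estimated correlation and without pregnancy 13). They included miR-412 at 2.58 ± 0.43, miR-376a at 2.09 and miR-495 at 1.65, while miR-127, the most abundant with miR-411a, did not differ past the threshold at -0.14 ± 0.16. The arms of miR-335, hosted by the imprinted MEST gene, were also higher, by 2.06 ± 0.35 for the 5p and 2.02 ± 0.37 for the 3p arm. In the list of smooth muscle and stroma 9 of 9 members were lower in fetal placenta (median -1.45, adjusted p = 0.000450; adjusted p = 0.198 with an estimated correlation), among them miR-143, which acts in contractile smooth muscle (-1.67 ± 0.29), and miR-145-minor (-2.98). All 3 measured miRNAs of the HOX clusters were lower (median -2.13, adjusted p = 0.0272; adjusted p = 0.129 with an estimated correlation), as were 8 of 11 of the let-7 family (median -0.64, adjusted p = 0.00602; adjusted p = 0.210 with an estimated correlation), which is tied to differentiation. All 4 members of the X-linked miR-424/450 cluster were higher in fetal placenta (median 0.95, adjusted p = 0.0382; 0.0525 without pregnancy 13, 0.0422 without it in the paired fit and 0.317 without it with an estimated correlation). The fits with an estimated correlation left out pregnancy 13. Adjusted over the list alone, the counts of members past the threshold were the same in these 5 lists.

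Among other miRNAs of large fold, miR-190a reached 557 ± 350 in fetal against 84.0 ± 77.0 CPM in maternal placenta (2.73 ± 0.49), miR-34c-5p differed by 1.84, miR-432 by 1.63, miR-154c by 1.61, and miR-203a-3p, a miRNA of stratified epithelia, and miR-452-3p by 1.57. Lower in fetal placenta were miR-204 (-2.59 ± 0.56), miR-195 (-2.40 ± 0.40) with its cluster partner miR-497, let-7b-5p (-2.20), miR-196b (-2.13), the miR-221-3p and miR-222 pair, which acts on the cell cycle inhibitor p27 (-1.91 and -2.05), miR-142-5p of blood cells (-2.01) and miR-125b-5p (-2.0). Without pregnancy 13 the folds grew, to -4.06 for miR-10a, -3.64 for miR-204 and 2.40 for miR-410. All 163 calls then stayed past the threshold with their sign, their median absolute log2 fold change moved from 1.03 to 1.2, and 171 miRNAs passed.

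**Figure D2:**
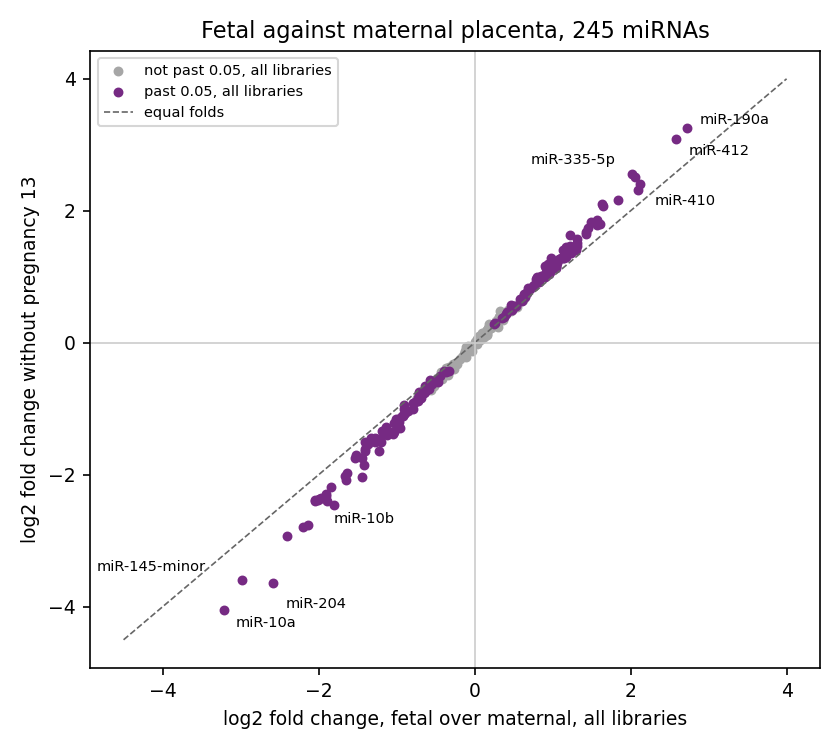
log2 fold change of fetal over maternal placenta per miRNA without pregnancy 13 (vertical) against all libraries (horizontal); each of 245 points is 1 miRNA, purple if past the threshold in all libraries, and the dashed line marks equal folds. The points lie on the steeper side of that line, and the median absolute fold of the 163 purple points is 1.2 without pregnancy 13 against 1.03 with it.

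The effect of the deletion in fetal placenta was examined next. Red cell miRNAs stood higher in deletion than in control fetal placenta as a group, and so did, by a small amount, the imprinted DLK1-DIO3 miRNAs. Both shifts passed a list test with a preset correlation and neither passed with an estimated one, and no single miRNA passed the main test. At the preset correlation at least 1 list of either tissue also passed in 98 random splits of the pregnancies, among 100 with the real one included. Shares of short and long listed sequences, at most an indirect sign of RNA quality, moved with the groups: sequences of 18 nt or shorter took 0.241 ± 0.0384% of counts in deletion and 0.175 ± 0.0279% in control libraries (exact permutation p = 0.00758), and those of 26 nt or longer 0.198 ± 0.101% and 0.0848 ± 0.0308% (exact permutation p = 0.00631). Without pregnancy 13 the control shares were 0.179 ± 0.0289% of short and 0.0940 ± 0.0204% of long ones (exact permutation p = 0.0130 and 0.0152). The long share rests on 17 listed sequences, and RNA quality itself was not measured here. By set, pregnancy 13 left out, the short ones took 0.171 ± 0.0218% in set 1 and 0.237 ± 0.0374% in set 2, and the long ones 0.0810 ± 0.00935% and 0.192 ± 0.0879%. The deletion library of set 1 had 0.193% of short and 0.0759% of long ones. miR-451, an erythroid miRNA matured by Argonaute 2, had 3608 ± 2164 CPM (SD, n = 5) in deletion and 1328 ± 332 CPM (n = 7) in control fetal placenta, a log2 fold change of 1.44 ± 0.37 (SE; edgeR adjusted p = 0.483), with 4 of 5 deletion libraries above the control median. Its most frequent sequence was AAACCGTTACCATTACTGAGTTT, with 64.0% of its counts. miR-486, also abundant in red cells, had 4080 ± 1132 against 2716 ± 911 CPM (0.59 ± 0.25), and miR-144, transcribed with miR-451, 214 ± 181 against 35.6 ± 57.4 CPM (2.65 ± 1.13). edgeR's quasi-likelihood test placed 0 of 290 miRNAs past the threshold and 23 at an unadjusted p under 0.05. DESeq2 gave 0 and 34, the likelihood ratio test 1 (miR-451, adjusted p = 0.0490) and 24, and limma-voom with quality weights 65 and 104.

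All 4 erythroid members lay above 0 (median 1.34, camera adjusted p = 0.00208; adjusted p = 0.302 with an estimated correlation). Over all miRNAs 0 of the 4 passed the threshold and adjusted over the list alone 4 did. The members are miR-451, miR-486 and both arms of miR-144, which is transcribed with miR-451, so they are not 4 independent miRNAs. miR-144 had 0 to 7.10 CPM in fetal libraries of set 1 and 66.7 to 445 CPM in those of set 2. The blood content of the tissue pieces was not measured. The set of pregnancies moved with this group: with the set term miR-451 stood at 1.32, miR-144 at 1.13 and miR-486 at 0.56, and within set 2 miR-451 stood at 1.27. With the set term and pregnancy 13 left out the list's median was 0.85 (adjusted p = 0.0227, and adjusted p = 0.322 with an estimated correlation). Set 1 without pregnancy 13 holds 1 deletion library, in which miR-451 stood 1.22 and miR-143 0.81 above the 4 controls, values of a single library. Without deletion pregnancy 25 miR-451 passed at 1.68 (adjusted p = 0.0283). In the DLK1-DIO3 list 41 of 48 members lay above 0 (median 0.32, adjusted p = 3.61e-07; adjusted p = 0.554 with an estimated correlation), among them miR-410 with 9519 ± 1218 against 6645 ± 2658 CPM (0.52 ± 0.33). Without pregnancy 13 the list's median was 0.20 (adjusted p = 0.0112), and with the set term as well 0.12 (adjusted p = 0.0227). The adjusted p of these fits was 0.355 and 0.566 with an estimated correlation. miR-410 stood at 0.17 in the latter. No DLK1-DIO3 member passed, over all miRNAs or adjusted over the list alone (0 and 0 of 48). The direction of both lists was the same under each scaling.

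**Figure D3:**
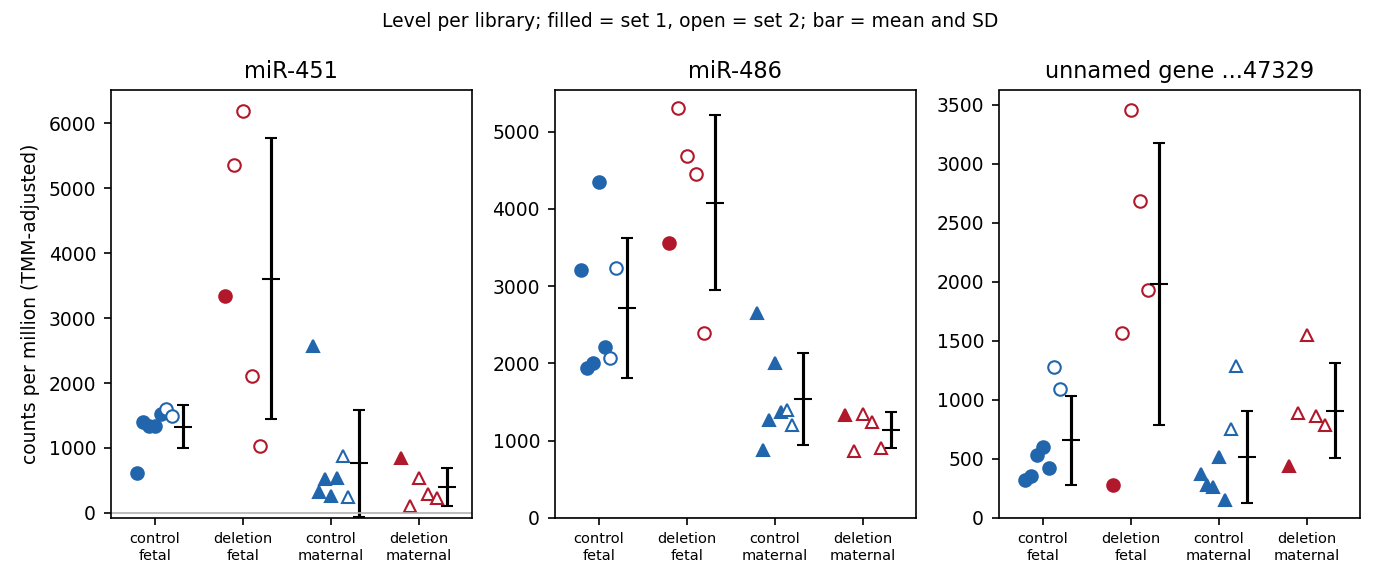
Level in CPM (TMM-adjusted) of miR-451, miR-486 and the unnamed gene ENSBTAG00000047329 in each library of the 4 groups; filled symbols are set 1, open symbols set 2, bars mean and SD. In fetal placenta the mean of miR-451 is 3608 with a deletion fetus and 1328 in controls, and that of ENSBTAG00000047329 is 1982 and 656, with set 2 fetal libraries above those of set 1 within either genotype for the latter.

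Other entries of smallest p in fetal placenta were 3 that stood higher with the deletion and resemble ribosomal RNA, ENSBTAG00000047329, ENSBTAG00000047154 and miR-2887, and 6 miRNAs that included the proliferation-linked miR-25 and miR-20a. ENSBTAG00000047329 had 1982 ± 1198 against 656 ± 376 CPM (1.59 ± 0.50, adjusted p = 0.499), but 0.45 with the set term. Its most frequent sequence, CCTAGCAGCCGACTTAGAAC (8.61% of its counts over 19 sequences), is known from textbook sequence as part of 28S ribosomal RNA. So are the only sequences of ENSBTAG00000047154 (29 nt) and of miR-2887 (17 nt), and no ribosomal reference was matched here. ENSBTAG00000047154 stood at 2.02 ± 0.64 and miR-2887 at 2.59 ± 0.91, and with the set term at 0.97 and 1.03. Lower were miR-423-3p (-0.51 ± 0.18), miR-103 (-0.55 ± 0.21), miR-25 (-0.39 ± 0.15), miR-15b-5p (-0.57 ± 0.22) and miR-20a (-0.42 ± 0.17), each in 5 of 5 deletion libraries below the control median, while miR-192 (0.34 ± 0.13) was above it in 5 of 5. With the set term miR-103 stood at -0.25, miR-25 at -0.21, miR-15b-5p at -0.37 and miR-423-3p at -0.33. The sequences of ENSBTAG00000047329 and of miR-7641, which resembles 5S ribosomal RNA, together took 0.206 ± 0.130% of counts in deletion and 0.0663 ± 0.0392% in control fetal libraries (exact permutation p = 0.0164), and 0.117 ± 0.0520% and 0.0706 ± 0.0574% in maternal ones (exact permutation p = 0.174). By set and without pregnancy 13 they took 0.0468 ± 0.0139% (5 libraries of set 1) and 0.206 ± 0.102% (6 of set 2) in fetal placenta, and 0.0362 ± 0.0156% and 0.139 ± 0.0370% in maternal placenta. miR-7641 was chosen after its values were seen, and ENSBTAG00000047329 was named for its small p in the same fetal comparison. The fetal p of their summed share is therefore no separate evidence.

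Over all libraries and without a set term no other group passed the threshold in fetal placenta, and 6 lists passed in other fits with the preset correlation. Of the miR-17/92 clusters, tied to proliferation, 2 of 12 members lay above 0 (median -0.21, adjusted p = 0.0630). This list passed at 0.0344 to 0.0478 without pregnancy 13, 17, 18, 22 or 24, at 0.0170 with the set term and at 0.0433 with pregnancy 13 left out as well, but with an estimated correlation the adjusted p of these fits was 0.227 to 0.474. Of let-7 3 of 11 lay above 0 (-0.33, and -0.21 without pregnancy 13; adjusted p = 0.1001). It passed without pregnancy 20 (0.0445) or 24 (0.0431), with an adjusted p of 0.554 and 0.534 with an estimated correlation. Of the miRNAs hosted by other imprinted genes 4 of 4 lay above 0 (0.39, and 0.25 without pregnancy 13; adjusted p = 0.150). They passed with the set term (0.0248) and with pregnancy 13 left out as well (0.0141), with an adjusted p of 0.309 and 0.169 with an estimated correlation. Of the epithelial miR-200 list 2 of 6 lay above 0 (-0.31, and -0.20 without pregnancy 13; adjusted p = 0.150). Of the imprinted genes' list miR-335-5p had 1454 ± 351 against 892 ± 327 CPM (0.71 ± 0.33), miR-335-3p stood at 0.39 ± 0.28 (0.22 without pregnancy 13), miR-483, hosted by IGF2, at 0.38 ± 0.45 (0.17 without pregnancy 13), and miR-296 at 0.06. The control mean of miR-335-5p includes the library labelled control fetal 13 at 201 CPM, against 819 to 1167 CPM in the other controls. miR-210, the main miRNA target of the hypoxia factor HIF, had 106 ± 22.8 and 107 ± 24.6 CPM (-0.02 ± 0.23), and the hypoxia list 4 of 7 members above 0 (median 0.02, and 0.28 without pregnancy 13; adjusted p = 0.528). The ciliated epithelium list, with miR-34b, miR-34c and miR-449a, had 0 of 5 above 0 (-0.40, adjusted p = 0.245), and the neuroendocrine list, with miR-375 and miR-7, 0 of 3 (-0.26, adjusted p = 0.395). The ciliated list passed without pregnancy 13 (0.0164), with the set term (0.0352) and with both changes (0.0141), and the neuroendocrine list without pregnancy 13 (0.0434) and with both (0.0141). With an estimated correlation the adjusted p of these fits was 0.227 to 0.427 for the ciliated and 0.169 to 0.227 for the neuroendocrine list. Pregnancy 13 set the sign of the HOX list, whose median was -1.23 with it and 0.09 without (adjusted p = 0.528), and of smooth muscle and stroma, -0.24 and 0.41 (0.888). With the set term and pregnancy 13 left out the HOX list passed as higher (0.32, adjusted p = 0.0433; adjusted p = 0.289 with an estimated correlation).

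For the remaining fetal lists the median and adjusted p were -0.20 and 0.395 for leukocytes (1 of 5 above 0), 0.15 and 0.5256 for miR-23/27/24 (4 of 6), 0.04 and 0.888 for miR-30 (6 of 10) and 0.01 and 0.888 for miR-424/450 (3 of 6), whose median lay below that of all miRNAs under library totals alone. The miR-181 list had 2 of 6 members above 0, a median of -0.21 and a mean of -0.09, while its test pointed up (0.913). Without pregnancy 13 the medians of miR-23/27/24, miR-30, miR-424/450 and miR-181 were 0.09, -0.06, -0.12 and 0.00424. Lists too short to test held miR-29a (-0.33) and miR-29b (0.22), miR-182 (0.24) and miR-183 (-0.03), the endothelial miR-126-5p (0.26) and miR-126-3p (-0.08), and miR-133a of striated muscle (-0.53). Their medians moved from -0.05 to -0.09 for miR-29, from 0.11 to -0.01 for miR-182 and miR-183 and from 0.09 to 0.27 for the endothelial pair when pregnancy 13 was left out. In all of these, and in the lists of the preceding group, 0 members passed over all miRNAs or adjusted over the list alone. Of the 10 most abundant miRNAs, miR-27b stood at 0.12 ± 0.18, miR-26a at 0.05, miR-22-3p at -0.14, miR-148a-3p at -0.17, miR-30a-5p at 0.05, let-7f at -0.33 (-0.18 with the set term) and miR-92a at -0.51 (-0.15 with the set term). The other 3 changed sign or size without pregnancy 13: miR-10b from -0.44 ± 0.41 to 0.17, miR-143 from 0.08 ± 0.40 to 0.63 and miR-21-5p from -0.72 to 0.15. The library labelled control fetal 13 also stood apart from the other controls for let-7f and miR-22-3p (highest) and for miR-30a-5p (lowest). The folds given above for these miRNAs include that library, and their values without it are not given here. miR-675 and miR-122, the latter the liver list, were not listed in either table.

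In maternal placenta, miRNAs of the miR-17/92 clusters and of the epithelial miR-200 list were lower, and those of smooth muscle and stroma, let-7 and miR-181 higher, with a deletion fetus. These group shifts passed a list test with a preset correlation and none passed with an estimated one, and no single miRNA passed the main test. Of the 2 length shares 1 moved with the groups: sequences of 18 nt or shorter took 0.283 ± 0.0466% of counts with a deletion and 0.2003 ± 0.0551% with a control fetus (exact permutation p = 0.0303; 0.0476 without pregnancy 13). The share of 26 nt or longer was 0.0791 ± 0.0254% and 0.0662 ± 0.0385% (exact permutation p = 0.523; 0.212 without pregnancy 13). By set, pregnancy 13 left out, the short ones took 0.185 ± 0.0176% in set 1 and 0.291 ± 0.0322% in set 2, and the long ones 0.0405 ± 0.00890% and 0.0884 ± 0.0207%. miR-214, a miRNA of mesenchymal cells, had 326 ± 130 CPM (SD, n = 5) with a deletion and 182.8 ± 41.96 CPM (n = 7) with a control fetus (0.84 ± 0.28; edgeR adjusted p = 0.531; 5 of 5 above the control median), and 0.45 with a set term and pregnancy 13 left out. miR-143 had 192137 ± 56740 against 118555 ± 51228 CPM (0.70 ± 0.38), and miR-92a of the miR-17/92 cluster 10480 ± 2207 against 14888 ± 3399 CPM (-0.51 ± 0.20). With a set term and pregnancy 13 left out these stood at 0.22 and -0.18. edgeR's quasi-likelihood test placed 0 of 265 miRNAs past the threshold and 18 at an unadjusted p under 0.05. DESeq2 gave 0 and 25, the likelihood ratio test 0 and 17, and limma-voom with quality weights 33 and 82.

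The miR-17/92 list had 2 of 11 members above 0 (median -0.35, camera adjusted p = 0.00321; adjusted p = 0.501 with an estimated correlation), with miR-25 at -0.35 ± 0.15, miR-93 at -0.54 ± 0.24 and miR-92b at -0.87 ± 0.41, and kept its call with a set term and pregnancy 13 left out (-0.23, 0.00363; adjusted p = 0.673 with an estimated correlation). The list of smooth muscle and stroma had 9 of 9 above 0 (0.66, 0.00316; adjusted p = 0.501 with an estimated correlation), with miR-199a-3p at 0.56 ± 0.31, but 0.22 (0.187) under that fit. The miR-200 list had 0 of 5 above 0 (-0.29, 0.0179; adjusted p = 0.501 with an estimated correlation) and was lost without pregnancy 15 (0.0663), 17 (0.108) or 26 (0.0585). let-7, with 11 of 12 above 0 (0.30, 0.0474), and miR-181, with 7 of 7 (0.27, 0.0474; for miR-181a 0.54 ± 0.29), had an adjusted p = 0.501 with an estimated correlation. With the set term let-7 was lost (0.225), and with pregnancy 13 left out as well both were, let-7 at a median of 0.11 (0.531) and miR-181 at 0.16 (0.160). let-7 was also lost without pregnancy 13 (0.166), 15 (0.146), 17 (0.175), 18 (0.0685), 22 (0.138) or 26 (0.115), and miR-181 without 13 (0.132), 14 (0.0670), 15 (0.108), 17 (0.108), 23 (0.155), 24 (0.0575), 25 (0.0916) or 26 (0.115). With the set term and pregnancy 13 left out miR-25 stood at -0.23, miR-93 at -0.29, miR-92b at -0.38, miR-199a-3p at 0.18 and miR-181a at 0.16. In these 5 lists 0 members passed over all miRNAs or adjusted over the list alone. Library totals alone shifted the median of all maternal miRNAs by -0.36, and relative to that shift each of the 5 lists kept its direction.

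The DLK1-DIO3 list in maternal placenta had 14 of 33 members above 0 and a median and mean of -0.06, while its test pointed up (adjusted p = 0.795). It passed with the set term (0.00988), without pregnancy 13 (median 0.22, 0.0149) and with both changes (0.23, 1.35e-05), with an adjusted p of 0.852, 0.593 and 0.673 with an estimated correlation. Of the other miRNAs of smallest p, miR-26a stood at 0.95 ± 0.35 (105160 ± 70363 against 54557 ± 19279 CPM), miR-29c, of a family that targets extracellular matrix, at 1.0 ± 0.40, miR-126-3p of endothelium at 0.64 ± 0.26 and miR-361-3p at 0.64. Lower were miR-296 (-0.72 ± 0.26), miR-449a of ciliated cells (-0.81 ± 0.30), miR-2285aa-minor (-1.16) and miR-6120-3p (-0.73). With a set term and pregnancy 13 left out, miR-26a stood at 0.40, miR-29c at 0.43, miR-126-3p at 0.30, miR-361-3p at 0.52, miR-296 at -0.64, miR-449a at -0.83, miR-2285aa-minor at -0.37 and miR-6120-3p at -0.30. miR-10b had 248164 ± 131947 against 161552 ± 61534 CPM (0.62 ± 0.39, and 0.24 in that fit). miR-451 had 400 ± 289 against 764 ± 828 CPM (-0.93 ± 0.64), where the library labelled control maternal 13 had 2572 CPM and the other 6 controls 463 ± 243 CPM, so that it stood at -0.21 without pregnancy 13. miR-486 stood at -0.43 with and -0.24 without that pregnancy. miR-210 had 50.4 ± 19.7 against 69.8 ± 20.9 CPM (-0.49 ± 0.33), and -0.15 with a set term and pregnancy 13 left out. The arms of miR-335 stood at -0.55 (3p) and -0.21 (5p), and at 0.40 and 0.58 without pregnancy 13. miR-483 was not listed.

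The remaining maternal lists did not pass over all libraries. The median and adjusted p were -0.37 and 0.121 for miR-424/450 (0 of 4 above 0; median -0.15 without pregnancy 13), 0.72 and 0.192 for miR-29 (3 of 3), 0.16 and 0.238 for miR-23/27/24 (5 of 6), 0.41 and 0.279 for leukocytes (6 of 7), 0.06 and 0.448 for the HOX list (2 of 3; median -0.11 without pregnancy 13), -0.55 and 0.448 for the other imprinted genes (0 of 3; median 0.40 without pregnancy 13), 0.24 and 0.597 for hypoxia (5 of 8; median 0.06 without pregnancy 13) and -0.00366 and 0.928 for miR-30 (4 of 8; median 0.07 without pregnancy 13). miR-424/450 passed without pregnancy 20 (0.0366; adjusted p = 0.483 with an estimated correlation). The mean of the miR-30 list was -0.01 while its test pointed up, and its median relative to all miRNAs turned from above to below 0 under library totals alone. Lists too short to test had medians of -0.54 for miR-182 and miR-183, -0.68 for the erythroid pair, 0.64 for the endothelial pair and -0.86 for 2 miRNAs of ciliated cells, and held miR-133a (-0.80) and miR-375 (-0.65). Without pregnancy 13 the erythroid pair stood at -0.23, miR-182 and miR-183 at -0.35 and miR-375 at -0.38. Adjusted over the list alone, miR-296 (1 of 3 tested members of its list), miR-449a (1 of 2) and miR-133a passed, against 0 over all miRNAs. miR-133a was the only tested member of its list, so for it this adjustment changed nothing.

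Whether the deletion effect differed between tissues was tested directly. The red cell miRNAs had the smallest p, miR-451 with a difference of 2.42 ± 0.77 (SE, fetal minus maternal log2 fold change) and miR-486 of 1.13 ± 0.38, and both had an adjusted p of 0.776. miR-296 differed by 0.96 ± 0.43 and miR-424-5p by 0.81 ± 0.38. Without pregnancy 13, whose libraries were the lowest fetal and the highest maternal control for miR-451, the differences were 1.60 ± 0.62 for miR-451, 0.99 ± 0.36 for miR-486, 1.24 ± 0.40 for miR-296 and 0.53 ± 0.34 for miR-424-5p. With set terms as well they were 1.45, 0.81, 1.23 and 0.42. In all libraries these 4 were the miRNAs with an unadjusted p under 0.05, and they were chosen after their values were seen. edgeR's quasi-likelihood test placed 0 of 245 miRNAs past the threshold. DESeq2 gave 0 with 9 at an unadjusted p under 0.05, the fit with the replicate block 0 and 5, and that block without pregnancy 13 0 and 16. The erythroid, miR-200 and other list results above are therefore not shown to differ between the tissues.

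Single sequences (isomiRs, variants of a miRNA that differ at their ends) gave the same count as summed miRNAs. In fetal placenta 0 of 1070 passed edgeR's quasi-likelihood test, with 101 at an unadjusted p under 0.05, and DESeq2 gave 0 and 125. Without deletion pregnancy 15, 3 sequences of ENSBTAG00000047329 passed (1.94, 2.14 and 2.04), and without deletion pregnancy 25, 2 of miR-451 (1.70 and 1.54), names outside the rule and chosen after their values were seen. Pregnancy 15 is the only deletion pregnancy of set 1, so without it the deletion group comes from set 2 alone. The 3 calls of ENSBTAG00000047329 therefore do not separate genotype from set. In maternal placenta 0 of 1024 passed, with 86 at an unadjusted p under 0.05, and DESeq2 gave 0 and 113. By class, canonical sequences took 38.5 ± 1.56% of deletion and 40.4 ± 2.22% of control fetal counts (exact permutation p = 0.130), and sequences shortened at the 3' end 27.7 ± 1.52% and 27.02 ± 3.93%. Controls other than pregnancy 13 had 25.6 ± 0.907% of the latter (exact permutation p = 0.0216, adjusted p = 0.106) and 41.1 ± 1.49% of canonical sequences. In maternal placenta sequences extended at the 3' end took 7.40 ± 0.966% with a deletion and 8.59 ± 0.448% with a control fetus, the smallest exact permutation p of the 14 class tests (0.0126, adjusted p = 0.177). None of the 14 passed after adjustment. Without control pregnancy 26, 2 passed, this share and that of fetal sequences without a canonical reference (exact permutation adjusted p = 0.0455 each), the latter at 18.9 ± 0.658% against 16.4 ± 3.06% in all libraries (exact permutation p = 0.0518) and against 17.5 ± 1.197% without pregnancy 13 (exact permutation p = 0.0433, adjusted p = 0.121). Pregnancy 26 is 1 of the 2 controls of set 2, and both shares also differed by set: pregnancy 13 left out, set 1 had 8.57 ± 0.243% and set 2 7.496 ± 0.909% of the former, and 17.2 ± 0.892% and 18.98 ± 0.698% of the latter. Permuted within the sets, in all libraries, both had an exact permutation p of 0.0778 (adjusted p = 0.285).

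The authors' deposited table for fetal placenta holds 29 of 1070 sequences past an FDR of 0.05, all higher with the deletion, with a median log2 fold change of 1.63. Of these 13 belong to ENSBTAG00000047329 and 5 to miR-451, 2 each to the arms of miR-136, and 1 each to miR-1185, miR-144, miR-19a, miR-2887, miR-2892, miR-301a and miR-376a. In the authors' deposited table for maternal placenta 9 of 1024 passed, all higher, with a median of 3.26: 4 of miR-7641 and 1 each of miR-101, miR-142-3p, miR-142-5p, miR-2478 and miR-2892. These names come from that table and not from the naming rule. From the same counts, the quasi-likelihood fit gave those sequences medians of 1.54 (interquartile range 1.29 to 1.67) and 1.47 (1.34 to 1.72), and the fit with the set term 0.55 and -0.07. The miR-144 sequence stood at 4.65 in the authors' deposited table (FDR 0.00146), at 2.71 in the quasi-likelihood fit and at 1.18 with the set term. The miR-451 sequences ran from 1.26 to 1.52 in the authors' deposited table and from 1.32 to 1.68 with the set term. In control libraries alone the same sequences stood higher in set 2 than in set 1 by a median of 1.27 (fetal) and 3.85 (maternal) on the log2 scale.

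**Figure D4:**
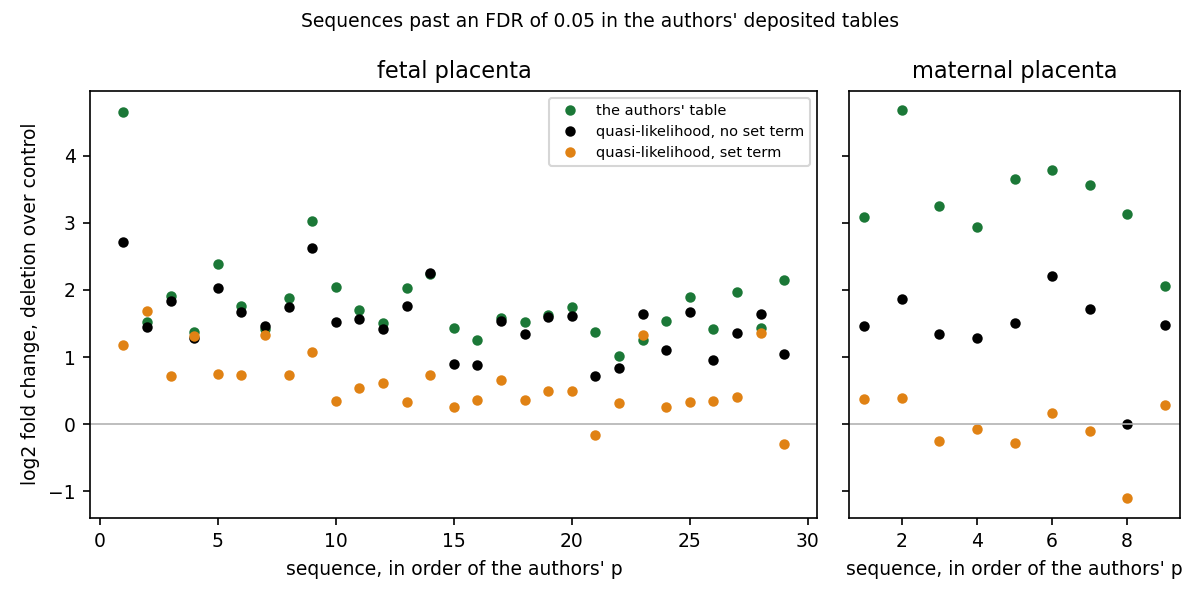
log2 fold change of deletion over control (vertical) for each of the 29 fetal and 9 maternal sequences past an FDR of 0.05 in the authors' deposited tables, in order of the deposited p (horizontal); green points are the deposited values, black points the quasi-likelihood fit and orange points that fit with the set term. The median goes from 1.63 deposited to 1.54 and 0.55 in fetal placenta and from 3.26 to 1.47 and -0.07 in maternal placenta.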

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

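The test for exchanged tissue labels, the test of down-weighted values, the tests with sets read from 1 tissue alone and all fits with a set term or with the likelihood ratio test were chosen only after the results they bear on were seen.

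A library stood apart from its group in 62 of 224 groups of levels, totals and shares, or 27.7%, and 50 of the 62 lay in a library of pregnancy 13. Chance gives about 5% where values are normally distributed, which was not tested for these levels. Values below are the gap to the nearest library divided by the range of the group. In the fetal deletion comparison the library labelled control fetal 13 was highest for let-7f (0.660), miR-10b (0.910), miR-143 (0.864), miR-15b-5p (0.714), miR-21-5p (0.960) and miR-22-3p (0.703). It was lowest for miR-30a-5p (0.703), miR-335-3p (0.690), miR-335-5p (0.640), miR-451 (0.724) and miR-483 (0.728). The library labelled control maternal 13 was lowest for miR-10b (0.590) and miR-21-5p (0.661) and highest for miR-335-3p (0.8003) and miR-335-5p (0.741). With both tissues scaled together, control fetal 13 was highest for let-7b-5p (0.909), miR-10a (0.824), miR-10b (0.909), miR-125b-5p (0.716), miR-142-5p (0.638), miR-145-minor (0.909), miR-195 (0.915), miR-196b (0.920), miR-204 (0.961), miR-221-3p (0.869), miR-222 (0.867) and miR-497 (0.697). It was lowest for miR-203a-3p (0.763), miR-335-3p (0.709), miR-335-5p (0.657) and miR-495 (0.570). Control maternal 13 was then highest for miR-154c (0.672), miR-190a (0.755), miR-203a-3p (0.6995), miR-335-3p (0.786), miR-335-5p (0.721), miR-34c-5p (0.791), miR-412 (0.579), miR-432 (0.758) and miR-495 (0.791), and lowest for miR-10b (0.622), miR-195 (0.569) and miR-497 (0.741).

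Class shares set pregnancy 13 apart as well. In the library labelled control fetal 13 the shares of sequences with a changed 3' end (0.855) and a shortened 3' end (0.796) were highest, and that of sequences with no reference (0.6501) lowest. In control maternal 13 the shares with a changed (0.681) and a shortened 3' end (0.780) were lowest, and those of canonical sequences (0.767) and of sequences with no reference (0.642) highest.

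Other libraries that stood apart were deletion fetal 17, lowest for miR-25 (0.791) and highest for miR-145-minor (0.716), miR-204 (0.712) and the share of sequences with no reference (0.735). Deletion fetal 18 was highest for ENSBTAG00000047154 (0.726) and lowest for the share with a shortened 3' end (0.798), and control fetal 26 was highest for miR-2887 (0.762). In maternal placenta deletion 15 was highest for miR-2285aa-minor (0.740) and miR-6120-3p (0.788), deletion 17 highest for miR-26a (0.742), deletion 25 lowest for miR-296 (0.858) and control 20 highest for miR-221-3p (0.663).

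The first pattern weighed is that both libraries of pregnancy 13 lay on the side of the other tissue. A mixture of both tissues in each library is argued against, since over 28 miRNAs 4-fold apart between tissues the median share of the other tissue's level was 0.983 in the library labelled fetal 13 and 1.01 in the library labelled maternal 13, where a mixture would have given a share between 0.2 and 0.8. An exchange of the 2 tissue labels of this pregnancy may account for the pattern. The position of 0.980 lay within the range of the other maternal libraries (0.786 to 1.27), and that of 0.0554 lay above the highest of the other fetal libraries (0.0450) but within their range widened by 1 SD. At which step an exchange could have happened stays open, and no biological explanation was tested. The labels were kept as given in every comparison.

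The second pattern is the division of the 12 pregnancies into 2 sets. The deletion as its cause is argued against, because control pregnancies lay in both sets, and 71 fetal and 41 maternal miRNAs passed the threshold between the sets in control libraries alone (4 of set 1 and 2 of set 2, without pregnancy 13). The sets were read for this from the libraries of the other tissue alone, which gave the same sets. Depth is argued against too, as both libraries of 12 of 12 pregnancies stayed on their side after every library was thinned to 291140 counts. A library or sequencing batch shared by both tissues of a pregnancy is a candidate explanation, since, with the sets read from fetal libraries alone, the set differences per miRNA in fetal and in maternal libraries correlated across 245 miRNAs with r = 0.840 (Spearman rho 0.792; exact permutation p = 0.00433 over 462 arrangements of the pregnancies; pregnancy 13 left out). A difference between the cows would give this as well, so a batch is not shown. A difference in RNA quality, which was not measured, stays open too, as sequences of 18 nt or shorter took 0.185 ± 0.0176% of maternal counts in set 1 and 0.291 ± 0.0322% in set 2. So does a biological difference between the cows or in the gestation day at collection, which the labels give only as a range and which was not tested.

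The third pattern is the excess of sequences past the threshold in the authors' deposited tables, 29 fetal and 9 maternal, over 0 and 0 by edgeR's quasi-likelihood test, with 101 and 86 at an unadjusted p under 0.05, and 0 and 0 by DESeq2. The choice of the likelihood ratio test alone is argued against, since from the same counts it passed 0 fetal and 0 maternal sequences, with 115 and 100 at an unadjusted p under 0.05. The unequal spread of the sets over the genotypes may account for part of the fold changes, since their medians were 0.55 and -0.0709 with the set term, against 1.54 and 1.47 without it, although 27 of the 29 fetal sequences still lay above 0. Down-weighting of values that stand apart within their genotype may account for the calls: a likelihood ratio fit with outlier-robust dispersions passed 40 and 26 sequences, among them 29 of the 29 and 9 of the 9. Its fold changes correlated with the deposited ones with r = 0.9998 and 0.998 across sequences. It gave the called sequences a mean weight of 0.715 and 0.413 in the libraries of each genotype's smaller set against 0.977 and 0.993 in the others. The low weights were those of controls 23 and 26, at 0.630 and 0.626 in fetal and 0.164 and 0.0938 in maternal placenta. Deletion 15, the smaller set of its genotype, had 0.887 in fetal placenta, near deletion 18 (0.883). In maternal placenta it had 0.981, above deletion 17 (0.950). An effect of the deletion on miR-451, whose sequences kept their fold with the set term, stays open as a biological explanation.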

How the results depend on the processing

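All fits with a set term, within a set, without pregnancy 13 combined with these, by the likelihood ratio test, or with an estimated correlation combined with these or with leaving out a replicate were chosen only after the data were seen. So were the paired fits without pregnancy 13 and all list tests between tissues. The other alternatives were planned.

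Counts of miRNAs past the threshold in the deletion comparisons stayed at 0 under other scaling, DESeq2, other filters, canonical sequences alone and the set term, in both tissues. limma-voom with quality weights gave 65 in fetal (36 higher, 29 lower) and 33 in maternal placenta (18 higher, 15 lower). In fetal placenta the likelihood ratio test gave 1, set 1 without pregnancy 13 gave 2, and leaving out each replicate gave 0 to 1. For fetal sequences, set 1 without pregnancy 13 gave 13 (12 higher, 1 lower), the likelihood ratio test with robust dispersions 40, and leaving out each replicate 0 to 3. That robust test gave 26 maternal sequences (23 higher, 3 lower). The cause of these moves was not tested, except that by construction the voom fit weights libraries and the robust fit weights single values. Set 1 without pregnancy 13 holds 5 libraries of each tissue, 1 of them with the deletion, assumed to vary like the controls, so its counts are no replicated test. The voom fit gave its lowest fetal weights to control 13 (0.106), deletion 15 (0.472), control 26 (0.555) and control 23 (0.673), against 1.07 to 2.51 in the others. In maternal placenta these were control 13 (0.142), deletion 17 (0.469), deletion 15 (0.534), control 26 (0.712) and control 23 (0.759), against 1.13 to 2.47. Most of them are of their genotype's smaller set, so the 65 and 33 do not separate genotype from set. The 146 results of single miRNAs in the deletion comparisons had 3584 other values. Of these, 3358 stayed on their side of the threshold with their direction or within 1 SE of the main value, 184 moved and 42 passed newly. A change of sign was seen in 336 values.

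Of the lists, 7 passed in the 2 tissues, and 0 by directional fry and 0 by mixed fry. With an estimated correlation 0 passed over all libraries, 0 when each replicate was left out, 0 with the set term and 0 with the set term and pregnancy 13 left out. With the preset correlation the set term gave 10, with or without pregnancy 13, and leaving out each replicate gave 4 (without 15 or 26) to 9 (without 13 or 20). The miR-10/196 list in fetal placenta reversed from lower to higher with the set term and pregnancy 13 left out (adjusted p = 0.0433, against 0.528 in all libraries, and 0.289 with an estimated correlation). Its median was -1.23 over all libraries and 0.09 without pregnancy 13, so leaving out that pregnancy was enough to turn its sign. With the set term alone its test also pointed up (camera adjusted p = 0.815). Why the list passed with both changes was not tested. Class shares passed in 0 tests, and in 0 to 2 when each replicate was left out, with 2 without pregnancy 26.

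For fetal against maternal placenta the count of 163 miRNAs ran from 151 to 171 when each pregnancy was left out, was 164 with median-ratio factors and 166 with DESeq2, and 0 of 456 values of named miRNAs changed sign, while 1 call ended, that of miR-335-3p, to which DESeq2 gave no p. With the replicate block, the paired fit, 178 miRNAs passed (93 higher, 85 lower), 163 of them shared with the unblocked fit, and 163 passed with the pregnancy as a random block. The paired fit of the difference between tissues gave 0 miRNAs, and 0 with the random block. Without pregnancy 13 the paired fit passed the tissue lists miR-30 (0.0422, against 0.0645 unpaired) and miR-424/450 (0.0422, against 0.0525). Unpaired and with an estimated correlation their adjusted p was 0.159 and 0.317. Simulated folds of log2 1 were recovered for 32% of changed maternal sequences, among 1024, and for 61% of changed maternal miRNAs, among 265. Counts, the number of features and the share of them changed differ between these, and which of them limited the recovery was not tested. Leaving out sequences of several miRNAs was not run, because each sequence carries 1 symbol.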

Other observations

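The tests of the lists between fetal and maternal placenta and the ranking of splits by unadjusted p were chosen only after the data were seen, and the other counts over splits of the samples were planned.

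Several miRNAs known from other cell types differed between fetal and maternal placenta. Both arms of miR-126, which is expressed by endothelium and made up a list too short to test, were lower in fetal placenta, the 3p arm at 3232 ± 935 against 7755 ± 2815 CPM (SD, n = 12 each; log2 fold change -1.28 ± 0.17 SE) and the 5p arm at -1.13 ± 0.23. Of the leukocyte list 4 of 5 members were lower (median -1.20), with miR-142-5p at -2.01 and miR-146b at -0.73, while miR-342 stood at 0.08, and the list missed the threshold (camera adjusted p = 0.0919; adjusted p = 0.198 with an estimated correlation and without pregnancy 13). miR-451 was higher by 1.22 ± 0.39 and miR-486 by 0.68 ± 0.19, the 2 erythroid members measured in both tissues. miR-182 and miR-183, of an epithelial and sensory cluster, were both higher (1.05 ± 0.19 and 1.11 ± 0.26), as were miR-375 of endocrine cells (1.0 ± 0.26), miR-34c-5p, 1 of 2 ciliated-cell miRNAs, and miR-133a of striated muscle (0.85). Of the miR-200 list 2 of 5 were higher, miR-141 at 0.96 ± 0.19 and miR-200c at 0.70 ± 0.24, and 1 lower, miR-200b-3p at -0.69 ± 0.18 (adjusted p = 0.491).

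Of the hypoxia list 2 members were higher and 4 of 7 lower (median -1.16, adjusted p = 0.491), with miR-21-5p at -1.90 ± 0.33, while miR-210 itself stood at 0.16 ± 0.20. In the miR-30 family 5 of 8 were higher, miR-30a-5p by 0.58 ± 0.12 (adjusted p = 0.0898 for the list, and 0.0422 in the paired fit without pregnancy 13, against 0.159 with an estimated correlation without that pregnancy). Of miR-181 3 of 6 were lower, miR-181a at -1.52 ± 0.20 (0.308), of miR-29 1 of 2, miR-29a at -0.71 ± 0.17, and of miR-23/27/24 2 were higher and 2 lower of 6 (median -0.04, mean 0.04, test pointing down, 0.950), miR-27b at 0.49 ± 0.12 and miR-27a-3p at -0.58 ± 0.15. In the miR-17/92 clusters 3 were higher and 1 lower of 11 (0.491), and 1 passed adjusted over the list alone. Of the other imprinted genes 2 of 3 were higher (0.266), both arms of miR-335. In the remaining lists the counts adjusted over the list alone equalled those over all miRNAs.

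Random splits of the pregnancies into groups of 7 and 5, 100 with the real one included, were set beside the real split. Where the real count past the threshold was 0, for miRNAs and sequences of both tissues and for the difference between tissues, 100 of 100 splits give as many by construction, so these counts say nothing on chance. The highest other splits gave 45 fetal miRNAs, 130 fetal sequences, 47 maternal miRNAs, 122 maternal sequences and 0 miRNAs for the difference. The first 4 of these came from 1 split, the only one drawn with 0 of its 5 pregnancies from set 2. Such counts point to a structure of the samples. The sets were read from the same values, so the place of that split among them is no further evidence. Counts at an unadjusted p under 0.05 do not exclude chance: 26 of 100 splits gave as many fetal miRNAs as the real 23 (highest other 87), 22 as many fetal sequences as the real 101 (331), 25 as many maternal miRNAs as the real 18 (95), 19 as many maternal sequences as the real 86 (363) and 66 as many miRNAs for the difference as the real 4 (71). For the lists 17 of 100 splits gave as many as the real 7, the highest other being 10, so chance is not excluded. At least 1 list passed in 98 of the splits other than the real one. A list that passes with the preset correlation is therefore not unusual in random groupings. For fetal against maternal placenta 1 of 100 splits of the libraries gave as many as the real 163, which was the real split, the highest other giving 1. The real count thus lay far above those of the other splits drawn, and 100 splits cannot show a share below 1 of 100. Tissue labels were redrawn over the libraries of a genotype and not exchanged within pregnancies, so these splits ignore the pairing.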
